A study of Rattus norvegicus with 24 samples.

How the data were processed

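RNA from rat hippocampus was measured on 24 Affymetrix rat U34 (set A) arrays, 2 for each combination of arm (SHAM, TOL) and hours after the operation (0, 1, 3, 12, 24 and 48 h). The groups, the tests, the gene lists, the rule for naming genes and most alternatives were chosen before the data were examined. The deposited values are linear, background-subtracted intensity values made by the authors, 1 per probe set and array. The software, its version and any scaling are not given in the sources used here. Of the values of each array, 21.9% to 24.5% lay at or below 0. The medians of the arrays ranged from 51.6 to 85.6 units and their 2% trimmed means from 173 to 255. Since the trimmed means differed by more than 5%, the arrays were quantile normalised. Each array's experiment file gave the hybridisation day and time (2 days of 12 arrays) and a fluidics record, and all arrays came from 1 chip lot. The fluidics run was not recorded but inferred. Arrays whose recorded times followed each other by at most 5 minutes were taken as 1 run, which gave 6 runs.

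Values were floored at the 25th percentile of all values (3.49 units) and taken to log2. Of 8799 probe sets, the 59 Affymetrix controls were left out, and a probe set was tested if it lay above the floor on both arrays of at least 1 group, which left 7092. By the annotation used, 7018 probe sets matched 1 gene, 308 several and 1473 none. Counts are of probe sets unless genes are named, and each of the 4083 genes was represented by its tested probe set with the highest mean. The signal over background set the precision. The 99th percentile of the 1978 probe sets whose mean was at or below 0 was 41.1 units, which served as the noise level. Where both arrays of a group lay below it, the fold is given as a lower bound computed with the noise level, and no fold is given where both groups did. For such genes a fitted log2 difference, called so in the text, only shows how far another setting or a left-out array moves it. No 2 arrays held the same values, and no value column was left without a sample.

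A mean per group was fitted with limma 3.58.1 in R 4.3.3, with default empirical Bayes moderation (12 residual degrees of freedom, 1.47 prior), so that all 12 groups share an estimate of the spread. Moderated F tests covered the 5 later times against 0 h in SHAM, the same in TOL, and the difference between these time courses (interaction). Limma's moderated test was used for the mean difference TOL minus SHAM over the 6 times, for each single time against 0 h, for TOL against SHAM at each time and for single interactions. Tests are two-sided, and p-values were adjusted by Benjamini-Hochberg over the tested probe sets of each test, with a threshold of 0.05. A group left with 1 array when an array was left out is assumed to vary like the others. Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9 were used for figures.

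Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, over 26 lists with at least 5 measured genes. The lists were immediate early genes, heat shock proteins and chaperones, endoplasmic reticulum stress, growth factors and neurotrophins, astrocyte markers, reactive glia, microglia and macrophage markers, cytokines and inflammation, neuronal and synaptic markers, glutamate receptors, GABA system and interneuron markers, voltage-gated ion channels, calcium handling, oligodendrocyte markers, endothelial and vascular markers, choroid plexus and ependymal markers, blood cell markers, antioxidant and metal-binding genes, apoptosis and p53 targets, hypoxia and glycolysis, cholesterol synthesis, cell cycle and proliferation, interferon response and class I antigen presentation, ribosomal proteins, proteasome subunits and oxidative phosphorylation. Each was tested in 22 contrasts, and adjusted over all lists and contrasts together. Some genes stand on more than 1 list. Member counts are given over all probe sets tested and adjusted over the list alone.

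Genes were named by a fixed rule from those with 1 symbol. It took the 12 largest rises and 12 largest falls of each time course among genes passing the F test and the single contrast with both arrays beyond both 0 h arrays, the 10 highest and 10 lowest mean arm differences with the same sign at 5 or more of 6 times, the 5 highest and 5 lowest at each time, the 12 smallest interaction p-values, and up to 4 members of each list and comparison by smallest p. Where fewer than 5 genes passed, the 5 with the smallest p are named as not passed. Some were left out for length. With the low floor, 1 group lay below the noise level for 23 of 24 genes named for SHAM and 21 of 24 for TOL. For 2 in TOL both did. After the data were seen, the rule was repeated with the floor at the 40th percentile (36.9 units). Of the genes reported, Dusp1 in SHAM, Fos in TOL, Nr3c2 and Tspo in both arms and Tef at 48 h were named only by that repeat. For Hspb1, Grin1, Jun at 48 h, Nr4a3 in SHAM, Itpr1 in SHAM and Sart1, 1 other probe set of the gene moved the other way.

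The alternatives were the deposited scale, median scaling, floors at the 10th and 40th percentile, a pseudocount in place of the floor, no filter, a filter requiring at least 12 arrays above the floor, the replicate number as a block, the hybridisation day as a fixed block, the fluidics run as a random block, trend and robust moderation, leaving out each array in turn, counts per gene, and, for lists, an estimated correlation, fry and the mean of a gene's probe sets. Added after the data were seen were the naming repeat, F tests of 1, 3 and 12 h alone, the arm difference over 1 to 24 h, additive models of time, arm and day, and list tests with the day as a block, under each scaling, floor and filter and without each array. The tests were also run on simulated data. Of probe sets changed 2-fold, 41.8% were recovered by the SHAM F test, 49.3% by the TOL F test, 17.9% by the interaction and 95.5% by the mean arm difference, with 14, 11, 5 and 14 false calls. At 4-fold the shares were 80.3%, 75.8%, 65.2% and 95.5%. A simulated list of 30 genes raised by 0.5 log2 was called (camera adjusted p = 1e-16), and 0 of the unchanged lists were. The simulated genes varied independently of each other, so this does not test the preset correlation or false list calls among correlated genes.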

Results

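Gene expression was measured in rat hippocampus with Affymetrix arrays at 0, 1, 3, 12, 24 and 48 h after an operation that caused ischemia. The arm called SHAM was described as sensitive to hypoxia and that called TOL as tolerant of it. The 12 combinations of arm and time held 2 arrays each, from a first and a second experiment, 24 in all. After filtering, 7092 probe sets covering 4083 named genes were tested. Arrays of one group correlated at r = 0.921 to 0.954 across probe sets, and the median replicate SD was 0.297 on the log2 scale. The number of arrays limits the precision. Nothing in the labels says that the arrays of a group came from separate animals, so the p-values measure only the spread between these samples, which may be technical. Levels are given below as normalised intensity in arbitrary units, as mean ± SD (n = 2), and log2 differences with their SE and the limma adjusted p. For every gene reported below as changed against 0 h or as different between the arms at a time, both arrays of one group lay beyond both arrays of the other, which groups of this size often do by chance.

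In the arm described as sensitive, each SHAM time was compared with 0 h. Immediate early genes, switched on without new protein synthesis, rose within 1 h. The AP-1 subunit gene Fos went from 161 ± 36.1 units at 0 h to 1780 ± 55.7 units at 1 h (log2 difference 3.48 ± 0.33, adjusted p = 4.6e-05). Its partner Jun rose from 159 ± 9.9 to 907 ± 34.6 units (2.51 ± 0.21, adjusted p = 1.2e-05), and the phosphatase gene Dusp1 from 147 ± 11 to 896 ± 136 units (2.60 ± 0.38, adjusted p = 0.0026). Egr2 was at least 7.83-fold higher, at 322 ± 4.95 units against a 0 h level below the noise level (adjusted p = 1.3e-06). Of the 32 measured immediate early genes, 7 rose at 1 h and 15 did so adjusted over the list alone (median log2 difference 0.69, adjusted p = 5.46e-18). At 3 h, 6 rose, and 12 rose and 1 fell adjusted over the list alone (median 0.46, adjusted p = 7.11e-08). Jun was still high at 48 h (678 ± 122 units, 2.08 ± 0.21, adjusted p = 4.6e-05). By then the nuclear receptor gene Nr4a3 had fallen to 140 ± 10.1 from 479 ± 3.42 units (-1.77 ± 0.19, adjusted p = 7.9e-05) and the ERK phosphatase gene Dusp6 to 332 ± 31.6 from 1030 ± 46.9 units (-1.64 ± 0.20, adjusted p = 0.00023).

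Heat shock proteins and other chaperones were higher in SHAM at every time from 1 h on. Hspa1a, an inducible chaperone gene, was below the noise level at 0 h and reached 2420 ± 340 units at 1 h, 5400 ± 81.4 units at 12 h and 1560 ± 39.3 units at 48 h. These levels were at least 58.6-fold, 131-fold and 37.8-fold higher (adjusted p = 1.2e-07, 1.8e-08 and 1.8e-07). At 24 h, Hsph1 stood at 6870 ± 134 against 1040 ± 76.2 units (2.72 ± 0.16, adjusted p = 2.5e-07). The small heat shock gene Hspb1 was at 2550 ± 9.14 against 322 ± 24.1 units (2.99 ± 0.33, adjusted p = 8e-05) and the mitochondrial chaperonin gene Hspd1 at 5070 ± 757 against 1130 ± 23.4 units (2.15 ± 0.15, adjusted p = 1.4e-06). Stip1, a co-chaperone gene, rose by 2.08 ± 0.17 (adjusted p = 4.8e-06). Of 23 measured members, 4, 7, 12, 12 and 9 rose at 1, 3, 12, 24 and 48 h, and 4, 8, 15, 17 and 12 did so adjusted over the list alone, where 1 member also fell at 48 h. The list's median difference was 0.22, 0.42, 1.06, 1.20 and 0.59 at these times, with adjusted p = 1.19e-05, 4.43e-09, 4.22e-19, 8.81e-18 and 2.14e-05. With an estimated correlation between genes the calls at 1, 3 and 48 h were lost (adjusted p = 0.163, 0.077 and 0.175 with an estimated correlation). Over both arms and all lists, 8 calls held with an estimated correlation, namely immediate early genes at 1 and 3 h and heat shock proteins at 12 and 24 h in each arm. The fitted Hspa1a difference depended on which 0 h array was used. At 1, 12 and 48 h it was 8.30, 9.47 and 7.67 without SHAM 0 h replicate 1 and 6.60, 7.76 and 5.97 without SHAM 0 h replicate 2.

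Some other stress genes rose in SHAM between 3 and 48 h. Neither the p53 target nor the hypoxia list passed camera at these times (lowest adjusted p = 0.193 and 0.0955). The prostaglandin synthase gene Ptgs2 rose from 177 ± 25 to 703 ± 174 units at 3 h (1.97 ± 0.22, adjusted p = 0.00021). Ppp1r15a reached 296 ± 15.9 from 83.3 ± 5.07 units at 12 h (1.83 ± 0.15, adjusted p = 7.2e-06). The p53 target Mdm2 rose to 322 ± 22.5 from 71.8 ± 4.83 units at 24 h (2.17 ± 0.17, adjusted p = 3.4e-06). Ccng1, also induced by p53, rose to 2370 ± 375 from 781 ± 132 units at 48 h (1.60 ± 0.21, adjusted p = 0.00035). The hypoxia gene Hif1a rose at 24 h (215 ± 33.7 against 106 ± 7.58 units, 1.01 ± 0.15, adjusted p = 0.00074). The collagen prolyl hydroxylase gene P4ha1 rose by 1.62 ± 0.20 (adjusted p = 0.00021). The organic anion transporter gene Slco1a4 fell at 3 h to 80.4 ± 0.221 from 329 ± 37.7 units (-2.03 ± 0.27, adjusted p = 0.0014).

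Calcium handling and synaptic genes fell in SHAM at later times. The calcium release channel gene Itpr1 fell from 1640 ± 96.4 units at 0 h to 461 ± 30.4 units at 48 h (-1.83 ± 0.14, adjusted p = 4e-06). The plasma membrane calcium pump gene Atp2b1 fell to 564 ± 43.7 from 1410 ± 86.8 units (-1.33 ± 0.18, adjusted p = 0.00046), and the hippocampal calcium sensor gene Hpca to 1560 ± 437 from 3970 ± 187 units (-1.38 ± 0.18, adjusted p = 3e-04). Of 37 measured calcium handling genes, 9 fell at 24 h and 11 at 48 h. Adjusted over the list alone, 9 fell at 24 h, and 17 fell and 2 rose at 48 h. The list's median was -0.31 and -0.40 (adjusted p = 0.00018 and 0.000109; adjusted p = 0.102 and 0.092 with an estimated correlation). Among 53 neuronal and synaptic markers, 11 fell and 3 rose at 24 h (16 and 4 adjusted over the list alone). The median was -0.32 (adjusted p = 0.00234, or 0.265 with an estimated correlation), and -0.21 with low means at the noise level. Neither this list nor glutamate receptors passed camera at 48 h (adjusted p = 0.0523 and 0.101). Prkcb, a protein kinase C gene, was at 1060 ± 23.9 against 2820 ± 71.1 units at 48 h (-1.41 ± 0.11, adjusted p = 4.7e-06).

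Glutamate receptor genes fell too. At 12 h, 2 of 22 measured members fell, and 7 did adjusted over the list alone (median -0.42, adjusted p = 0.00392; adjusted p = 0.265 with an estimated correlation). At 24 h, 4 fell and 6 did adjusted over the list alone (median -0.26, adjusted p = 0.0136; adjusted p = 0.334 with an estimated correlation), a call lost without SHAM 0 h replicate 2 or SHAM 24 h replicate 2 (adjusted p = 0.0564 and 0.0501). The NMDA receptor subunit gene Grin1 fell at 24 h to 36.3 ± 11.7 from 182 ± 19.2 units, at least 4.24-fold with arrays under the noise level set to it (adjusted p = 0.00054). The AMPA receptor subunit genes Gria1 and Gria2 stood at 110 ± 32.2 and 429 ± 22.2 units at 48 h, against 434 ± 82.7 and 981 ± 73.8 units at 0 h (-2.00 ± 0.30 and -1.19 ± 0.14, adjusted p = 0.001 and 0.00017). The GABA-A receptor gene Gabra5 fell at 48 h to 165 ± 9.23 from 557 ± 71.8 units (-1.75 ± 0.16, adjusted p = 2e-05). The neuropeptide gene Cck fell to 519 ± 45.8 from 1170 ± 44.5 units (-1.17 ± 0.15, adjusted p = 0.00038). Nr3c2, the mineralocorticoid receptor gene, fell at 24 h to 109 ± 35.5 from 532 ± 50.9 units (-2.32 ± 0.29, adjusted p = 0.00027). Oxidative phosphorylation genes were slightly lower. Of 58 measured, 1, 3, 5 and 10 fell at 3, 12, 24 and 48 h (1, 3, 6 and 12 adjusted over the list alone), with medians of -0.16, -0.19, -0.19 and -0.23 (adjusted p = 0.0029, 0.00011, 0.00278 and 0.00209; adjusted p = 0.579, 0.478, 0.579 and 0.565 with an estimated correlation). The 3 h call was lost without SHAM 0 h replicate 2. The respiratory complex genes Cox6b1 and Uqcr11 fell at 12 h by 0.65 ± 0.10 and 0.63 ± 0.11 (adjusted p = 0.0021 and 0.0054).

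Microglia and reactive glia markers rose in SHAM at 48 h. Ifitm3, on the reactive glia list, rose from 139 ± 18.9 to 685 ± 202 units (2.28 ± 0.26, adjusted p = 0.00013). The complement inhibitor gene Serping1 rose from 75.1 ± 4.48 to 183 ± 68.3 units (1.24 ± 0.20, adjusted p = 0.0019). The microglial gene Aif1 (Iba1) rose from 80.3 ± 8.09 to 158 ± 19.2 units (0.98 ± 0.16, adjusted p = 0.0022). Of 28 measured reactive glia genes, 8 rose and 9 did adjusted over the list alone (median 0.76, adjusted p = 7.27e-05; adjusted p = 0.388 with an estimated correlation). Of 31 measured microglia and macrophage markers, 9 rose, and 14 rose and 2 fell adjusted over the list alone (median 0.67, adjusted p = 0.00774; adjusted p = 0.354 with an estimated correlation). With group means below the noise level set to that level, the medians were 0.62 and 0.22. The reactive glia list had passed at 12 h too (3 rose, 3 rose and 1 fell adjusted over the list alone, median 0.30, adjusted p = 0.0143; adjusted p = 0.609 with an estimated correlation), but not without SHAM 0 h replicate 1 (0.0567). The microglia call was lost without SHAM 0 h replicate 2 or SHAM 48 h replicate 1 (adjusted p = 0.05 and 0.0849). The SHAM 48 h arrays lay far apart for osteopontin (Spp1), at 774 and 73 units (mean 424 ± 496, at least 5.78-fold above 0 h, adjusted p = 0.018). Its call was lost without SHAM 0 h replicate 1 or 2 (adjusted p = 0.0678 and 0.0874), and its fitted log2 difference was 1.13 without SHAM 48 h replicate 1 and 4.54 without replicate 2. The complement gene C1qb rose by 2.02 ± 0.45 (adjusted p = 0.011), a call lost without SHAM 0 h replicate 2 or SHAM 48 h replicate 1 (1.43 and 1.74, adjusted p = 0.11 and 0.0923), and by 2.62 without SHAM 0 h replicate 1. Tspo, a mitochondrial translocator gene used as a marker of glial activation, rose by 2.62 ± 0.48 (adjusted p = 0.0044), also lost without SHAM 48 h replicate 1 (2.06, adjusted p = 0.0503). The cell cycle kinase gene Cdk4 rose to 504 ± 7.74 from 234 ± 29.9 units (1.11 ± 0.19, adjusted p = 0.0023).

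Over the whole SHAM time course, 1110 probe sets (636 genes) changed by the F test, and 855 did with the hybridisation day as a block, of which 806 were among the 1110. Within the day that held all SHAM arrays but SHAM 48 h replicate 2, 858 did. By single times, 52 probe sets were higher and 6 lower at 1 h, 99 and 45 at 3 h, 218 and 194 at 12 h, 355 and 291 at 24 h and 435 and 442 at 48 h. These single-time counts depend on individual arrays. The 144 calls at 3 h became 92, 81 and 71 without SHAM 0 h replicate 1, SHAM 0 h replicate 2 and SHAM 3 h replicate 2. The 412 at 12 h became 241, 216, 202 and 176 without SHAM 0 h replicates 1 and 2 and SHAM 12 h replicates 1 and 2. The 646 at 24 h became 374, 330 and 413 without SHAM 0 h replicates 1 and 2 and SHAM 24 h replicate 2. The 877 at 48 h became 432, 409, 382 and 529 without SHAM 0 h replicates 1 and 2 and SHAM 48 h replicates 1 and 2, or 551 with the day as a block. The balance of directions depends on the scaling. With each array divided by its median, 57.5% of calls at 3 h, 40.8% at 24 h and 36.4% at 48 h were higher, against 68.8%, 55% and 49.6% after quantile normalisation. On the deposited scale, where the median of all probe sets at 48 h shifted by 0.18, 71.8% of the 48 h calls were higher.

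**Figure D1:**
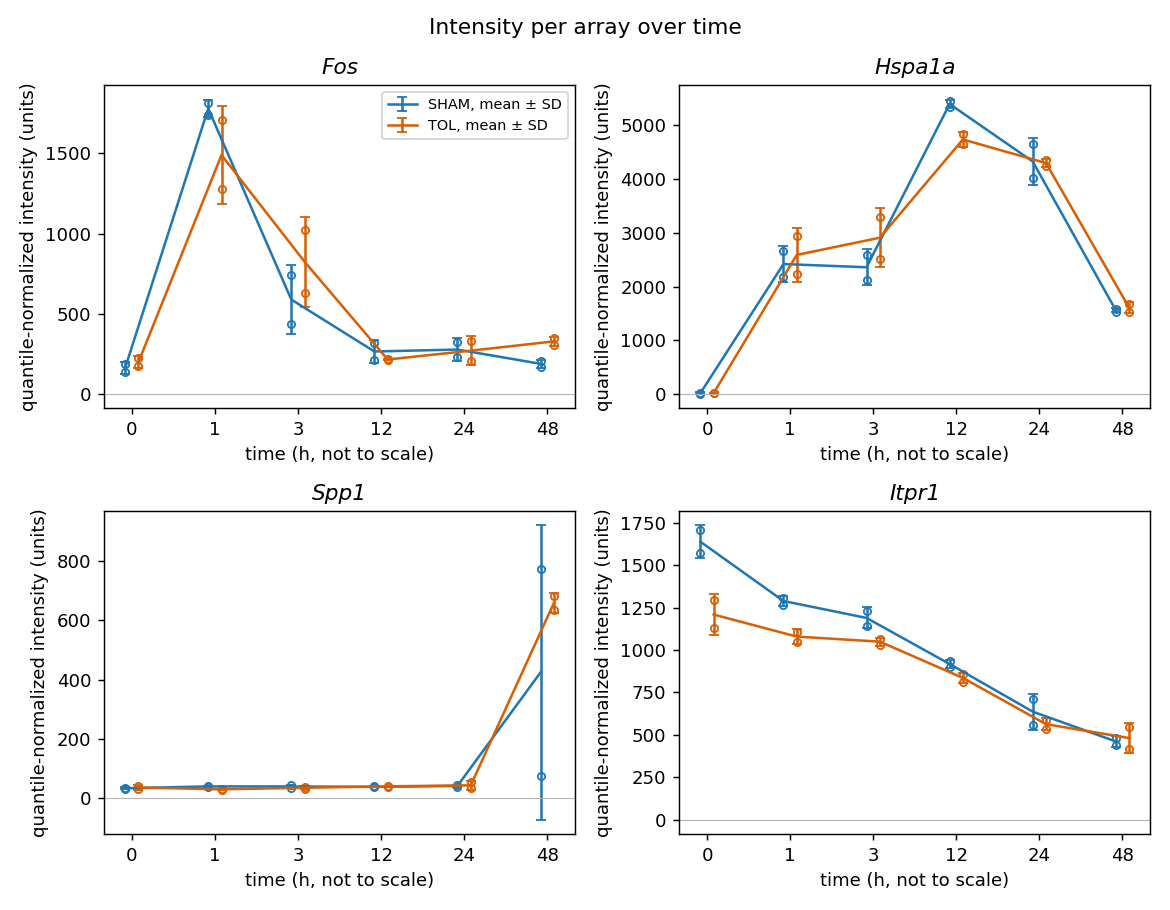
Normalised intensity in arbitrary units against hours after the operation (not to scale) for Fos, Hspa1a, Spp1 and Itpr1 in the SHAM and TOL arms, with an open point per array, lines through the mean of the 2 arrays and bars for the SD. Hspa1a lay below the noise level of 41.1 units at 0 h in both arms and reached 5400 units in SHAM and 4740 units in TOL at 12 h.

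The same comparisons were made in the arm described as tolerant. Immediate early genes rose at 1 h in TOL as well. Fos reached 1490 ± 306 from 197 ± 37.5 units (2.92 ± 0.33, adjusted p = 0.00022). Jun reached 1230 ± 9.97 from 175 ± 46.2 units (2.84 ± 0.21, adjusted p = 2.5e-06) and Dusp1 1140 ± 74 from 104 ± 61.1 units (3.58 ± 0.38, adjusted p = 0.00011). The Dusp1 difference was 2.95 without TOL 0 h replicate 1 and 4.22 without replicate 2. Egr2 was at least 7.09-fold higher (adjusted p = 4.9e-07). Of 32 measured members of the list, 11 rose at 1 h and 12 at 3 h, and 20 and 15 did so adjusted over the list alone (medians 0.85 and 0.65, adjusted p = 3.46e-19 and 1.76e-16). Plat, the tissue plasminogen activator gene, rose at 1 h from 168 ± 2.9 to 473 ± 39.7 units (1.49 ± 0.15, adjusted p = 5.9e-05), and Ppp1r15a by 1.70 ± 0.15 (adjusted p = 2.2e-05). At 48 h Jun was at 844 ± 7.17 units (2.30 ± 0.21, adjusted p = 2.3e-05), while Nr4a3 had fallen to 150 ± 32.4 from 393 ± 112 units (-1.38 ± 0.19, adjusted p = 0.001).

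Chaperone genes rose in TOL over the same hours. Hspa1a went from below the noise level to 2590 ± 498 units at 1 h, 4740 ± 134 units at 12 h and 1610 ± 107 units at 48 h, at least 62.4-fold, 115-fold and 39-fold higher (adjusted p = 1.8e-07, 3.4e-08 and 3.2e-07). Hspb1 reached 2880 ± 740 from 282 ± 40.3 units at 12 h (3.34 ± 0.33, adjusted p = 4e-05) and Hsph1 5760 ± 150 from 1000 ± 61.2 units (2.52 ± 0.16, adjusted p = 5e-07). The mitochondrial chaperonin pair Hspd1 and Hspe1 rose at 24 h by 2.12 ± 0.15 and 1.77 ± 0.17 (adjusted p = 1.6e-06 and 3.4e-05). Of 23 measured members, 4, 4, 11, 12 and 7 rose at 1, 3, 12, 24 and 48 h, and 4, 6, 14, 13 and 10 did so adjusted over the list alone. The medians were 0.13, 0.32, 0.96, 0.86 and 0.46, with adjusted p = 0.000332, 4.7e-08, 4.22e-19, 4.53e-17 and 2.02e-06. The calls at 1, 3 and 48 h were lost with an estimated correlation (adjusted p = 0.265, 0.092 and 0.136 with an estimated correlation). P4ha1 rose at 12 h by 1.73 ± 0.20 (adjusted p = 0.00016), Ptgs2 and Mdm2 at 24 h by 1.44 ± 0.22 and 1.39 ± 0.17 (adjusted p = 0.0013 and 0.00018), and Ccng1 at 48 h by 1.24 ± 0.21 (adjusted p = 0.0032).

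Calcium handling and neuronal genes fell in TOL at 24 and 48 h. At 48 h Itpr1 was at 481 ± 88.3 against 1210 ± 119 units (-1.34 ± 0.14, adjusted p = 9.4e-05). Atp2b1 was at 590 ± 131 against 1390 ± 165 units (-1.25 ± 0.18, adjusted p = 0.0011) and the calcineurin subunit gene Ppp3cb at 127 ± 26.6 against 346 ± 110 units (-1.43 ± 0.23, adjusted p = 0.0024). The calmodulin gene Calm2 had fallen at 12 h by 0.80 ± 0.12 (adjusted p = 0.0012). Of 37 measured calcium handling genes, 8 fell at 24 h and 12 at 48 h. Adjusted over the list alone, 10 fell and 1 rose at 24 h, and 14 fell at 48 h. The medians were -0.27 and -0.37 (adjusted p = 0.000766 and 0.000116; adjusted p = 0.136 and 0.092 with an estimated correlation), or -0.26 and -0.17 with low means at the noise level. Among 53 neuronal and synaptic markers, 8 fell and 2 rose at 24 h (11 and 2 adjusted over the list alone, median -0.19, adjusted p = 0.0194; adjusted p = 0.38 with an estimated correlation), a call lost without TOL 0 h replicate 2 or TOL 24 h replicate 1 (0.0721 and 0.0927). On the same list 13 fell and 1 rose at 48 h (17 and 1 adjusted over the list alone, median -0.23, adjusted p = 0.000177; adjusted p = 0.163 with an estimated correlation). At 1 and 3 h the same list passed in the other direction. At 1 h camera placed it higher (0 of 53 by limma, 3 adjusted over the list alone, median 0.24, or 0.16 with low means at the noise level, adjusted p = 5.87e-05; adjusted p = 0.136 with an estimated correlation). At 3 h, 2 rose and 2 did adjusted over the list alone (median 0.15, adjusted p = 0.0205; adjusted p = 0.38 with an estimated correlation). The call at 3 h was lost on the deposited scale (median -0.03, adjusted p = 0.215), with median scaling (0.0642) and without TOL 0 h replicate 2 or TOL 3 h replicate 2 (0.13 and 0.273). The member that rose at 48 h was the pentraxin gene Nptx2, which went from 358 ± 57.1 to 1050 ± 19.6 units (1.56 ± 0.27, adjusted p = 0.0034). Prkcb fell by 0.88 ± 0.11 (adjusted p = 0.00046), Gabra5 by 1.05 ± 0.16 (adjusted p = 0.0021) and Nr3c2 by 2.30 ± 0.29 (adjusted p = 0.00046). Of 22 glutamate receptor genes, 3 fell at 24 h, among them Gria2 by 0.96 ± 0.14 (adjusted p = 0.0012), and 4 did adjusted over the list alone (median -0.37, adjusted p = 0.0057; adjusted p = 0.283 with an estimated correlation). At 12 and 48 h 1 and 3 fell, and 5 and 5 did adjusted over the list alone (medians -0.26 and -0.28, adjusted p = 0.0159 and 0.0198; adjusted p = 0.348 and 0.354 with an estimated correlation). The calls at 12, 24 and 48 h were lost without TOL 0 h replicate 2 (adjusted p = 0.099, 0.0541 and 0.111), and that at 12 h without TOL 12 h replicate 2 (0.076). Of 58 oxidative phosphorylation genes, 0 and 1 fell at 1 and 3 h, the same adjusted over the list alone, and camera placed the list lower (medians -0.15 and -0.15, adjusted p = 0.00327 and 0.00234; adjusted p = 0.591 and 0.565 with an estimated correlation). The call at 1 h was lost without TOL 0 h replicate 1 or TOL 1 h replicate 2 (0.0781 and 0.105).

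Inflammatory and glial genes rose in TOL at 48 h. Spp1 went from 35.9 ± 8.75 to 658 ± 33.5 units, at least 15.8-fold (adjusted p = 0.0025). Tspo rose from 48.5 ± 14.6 to 612 ± 197 units (3.65 ± 0.48, adjusted p = 0.00066) and the class II antigen loading gene RT1-DMb from 57.2 ± 14 to 269 ± 38.6 units (2.25 ± 0.33, adjusted p = 0.0013). Galectin-3 (Lgals3) rose from below the noise level to 285 ± 62.7 units, at least 6.83-fold (adjusted p = 0.0014). Serping1 reached 339 ± 11.1 from 91.7 ± 4.64 units (1.89 ± 0.20, adjusted p = 1e-04) and Ifitm3 842 ± 263 from 212 ± 24.1 units (1.96 ± 0.26, adjusted p = 0.00069). Of 31 microglia and macrophage markers, 11 rose and 15 did adjusted over the list alone (median 0.68, or 0.58 with low means at the noise level, adjusted p = 4.4e-08; adjusted p = 0.077 with an estimated correlation). Of 28 reactive glia genes, 10 rose and 14 did adjusted over the list alone (median 0.69, adjusted p = 2.93e-08; adjusted p = 0.264 with an estimated correlation). Of 39 cytokine and inflammation genes, 7 rose and 13 did adjusted over the list alone (median 0.34, or 0.09 with low means at the noise level, adjusted p = 0.00125; adjusted p = 0.122 with an estimated correlation), among them the metalloproteinase inhibitor gene Timp2 (1.20 ± 0.14, adjusted p = 0.00018, but 0.0516 on the deposited scale).

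Genes of protein synthesis and of antioxidant defence rose in TOL at 48 h after normalisation. Of 36 ribosomal protein genes, 5 rose, and 5 did adjusted over the list alone (median 0.30, adjusted p = 2.93e-08; adjusted p = 0.092 with an estimated correlation). Of 35 antioxidant and metal-binding genes, 5 rose and 1 fell (9 and 1 adjusted over the list alone, median 0.32, adjusted p = 0.00327; adjusted p = 0.092 with an estimated correlation). The peroxiredoxin gene Prdx6 rose from 1030 ± 104 to 1580 ± 103 units (0.62 ± 0.11, adjusted p = 0.0034) and Rpl19 by 0.45 ± 0.10 (adjusted p = 0.013). The ribosomal protein list had been lower at 1 and 3 h. At each of these times 1 member fell, and 2 did adjusted over the list alone (medians -0.14 and -0.15, adjusted p = 0.00319 and 0.000759; adjusted p = 0.354 and 0.304 with an estimated correlation). The call at 1 h was lost with the day as a block (median -0.07, adjusted p = 0.113), and both were lost without TOL 0 h replicate 1 (0.179 and 0.0616). Without TOL 1 h replicate 1 that at 1 h was lost too (0.0596). At 24 h, 2 rose and 2 did adjusted over the list alone (median 0.16, adjusted p = 0.00141; adjusted p = 0.333 with an estimated correlation), a call lost on the deposited scale (median -0.04, adjusted p = 0.47), with median scaling (0.0875) and without TOL 0 h replicate 2 (0.111). At 48 h neither list passed on the deposited scale (medians -0.02 and 0.09, adjusted p = 0.175 and 0.0649), nor did Prdx6 and Rpl19 (0.29 and 0.14, adjusted p = 0.487 and 0.736). Rpl19 also missed the threshold with median scaling (adjusted p = 0.0728) and without TOL 0 h replicate 1 or TOL 48 h replicate 1 (adjusted p = 0.106 and 0.0896).

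Over the whole TOL time course, 828 probe sets (468 genes) changed by the F test. With the hybridisation day as a block 722 did, of which 680 were among the 828, and within the day that held all TOL arrays but TOL 0 h replicate 1, 686 did. By single times, 64 probe sets were higher and 24 lower at 1 h, 65 and 20 at 3 h, 178 and 139 at 12 h, 305 and 218 at 24 h and 297 and 235 at 48 h. The 88 calls at 1 h became 48 without TOL 0 h replicate 1 and 48 without TOL 1 h replicate 2, and the 85 at 3 h became 39 and 33 without TOL 0 h replicate 1 and TOL 3 h replicate 1. The 317 at 12 h became 110 and 157 without TOL 0 h replicate 1 and TOL 12 h replicate 2. The 523 at 24 h became 208, 171 and 216 without TOL 0 h replicate 1 and TOL 24 h replicates 1 and 2, and the 532 at 48 h became 199 and 234 without TOL 0 h replicate 1 and TOL 48 h replicate 1. With the day as a block the counts at 3, 12, 24 and 48 h were 46, 153, 326 and 344. On the deposited scale the median of all probe sets shifted by -0.16, -0.36, -0.15 and -0.28 at 3, 12, 24 and 48 h, and 60%, 25.3% and 28.8% of calls at 3, 12 and 48 h were higher, against 76.5%, 56.2% and 55.8% after quantile normalisation. Median scaling gave 43.1% at 48 h, and the day as a block gave 66.7% at 12 h. The fluidics records of the 4 TOL arrays at 24 and 48 h carry the word aborted. Without these arrays the F test of 1, 3 and 12 h called 235 probe sets in TOL and 297 in SHAM.

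**Figure D2:**
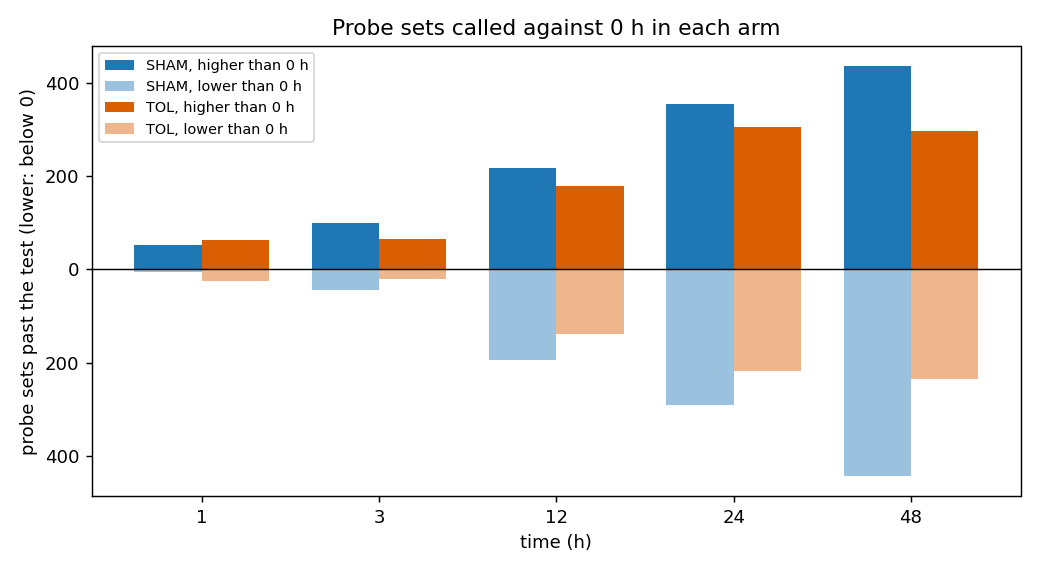
Number of probe sets higher (bars above 0) and lower (bars below 0) than 0 h at an adjusted p under 0.05, at each time in the SHAM and TOL arms. At 48 h, 435 were higher and 442 lower in SHAM, and 297 and 235 in TOL.

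The responses of the arms, which share no array, were then compared. Across the 4083 genes, which are not independent replicates, log2 differences from 0 h in SHAM and TOL correlated at r = 0.13, 0.17, 0.24, 0.38 and 0.42 at 1, 3, 12, 24 and 48 h. At 24 h, 100 genes rose in both arms and 48 fell in both, against 8.23 and 4.73 for independent lists of those sizes. At 48 h, 80 rose and 67 fell in both, against 9.72 and 8.18, and 1, 1, 4, 2 and 0 genes were called in opposite directions at 1, 3, 12, 24 and 48 h. Hspa1a, Jun, Ccng1, Ifitm3 and Serping1 were among those that rose in both arms at 48 h, and Itpr1, Atp2b1, Prkcb, Gabra5 and Nr4a3 among those that fell in both. The difference between the time courses, tested as an interaction, passed for 25 probe sets (14 genes). With 1 array left out at a time, that count was 42, 47, 41, 39, 53 and 44 without SHAM 1 h replicate 2, SHAM 3 h replicate 1, SHAM 24 h replicates 1 and 2 and TOL 12 h replicates 1 and 2.

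Among the 12 of these genes with the smallest p, Tef and Grk1 stayed above the noise level at every time in both arms. Tef encodes a PAR bZIP transcription factor. It was lower in TOL than in SHAM at 12 h (323 ± 15.2 against 532 ± 0.851 units, -0.72 ± 0.11, adjusted p = 0.011), at 24 h (280 ± 4.13 against 525 ± 1.06 units, -0.91 ± 0.11, adjusted p = 0.0013) and at 48 h (282 ± 5.08 against 461 ± 45.9 units, -0.71 ± 0.11, adjusted p = 0.0099), and its time courses differed (adjusted p = 0.023). With the day as a block the calls at 12 and 24 h were lost (-0.75 and -0.94, adjusted p = 0.167 and 0.0766), and on the deposited scale those at 12, 24 and 48 h were (-0.75, -0.82 and -0.93, adjusted p = 0.158, 0.202 and 0.0756). Single arrays also decide it. The call at 12 h was lost without SHAM 12 h replicate 2 (adjusted p = 0.0918). That at 48 h was lost without SHAM 48 h replicate 2 or TOL 48 h replicate 1 (adjusted p = 0.0702 and 0.0567), and the interaction call without SHAM 12 h replicate 2, TOL 24 h replicate 1 or TOL 24 h replicate 2 (adjusted p = 0.0547, 0.06 and 0.0544) or with median scaling (adjusted p = 0.0504). The ectonucleotidase gene Entpd2 (12 h, SHAM) and the potassium channel gene Kcnj10 (24 h, TOL) lay below the noise level. Entpd2 was at 118 ± 49.4 units in TOL, at least 2.73-fold higher (adjusted p = 5.1e-07). Kcnj10 was at 124 ± 0.371 units in SHAM, at least 3.01-fold lower in TOL (adjusted p = 1.5e-05). With the 40th percentile floor Entpd2 differed by 1.61 (adjusted p = 0.022) and Kcnj10 lost its call (0.102).

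TOL was then compared with SHAM over the mean of all times. Camkk2, a calcium/calmodulin-dependent kinase kinase gene, was lower in TOL (mean -1.13 ± 0.17, adjusted p = 0.0044), with the same sign at each of the 6 times, but both its TOL arrays lay below the noise level from 1 h on, so the size of the difference is uncertain. Ndufs8, a complex I subunit gene, and Igfbp2, a growth factor binding protein gene, were higher in TOL, also with the same sign at each time (0.87 ± 0.15 and 0.82 ± 0.15, adjusted p = 0.0068 and 0.0089). The sodium-calcium exchanger gene Slc8a1 was lower (-0.75 ± 0.13, adjusted p = 0.0068), but its 3 other probe sets differed the other way. Of 36 ribosomal protein genes, 9 were lower and 1 higher (14 and 3 adjusted over the list alone, median -0.11, adjusted p = 0.000477; adjusted p = 0.285 with an estimated correlation), among them Rps6 (-0.26 ± 0.04, adjusted p = 0.0061) and Rps3a (-0.23 ± 0.04, adjusted p = 0.01), which did not pass on the deposited scale (-0.23 and -0.20, adjusted p = 0.146 and 0.236). In all, 335 probe sets were higher and 325 lower in TOL (384 genes). With the values as deposited 100 passed, 76% of them higher.

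The arm nearly coincides with the day of hybridisation. The first day held every SHAM array but SHAM 48 h replicate 2, together with TOL 0 h replicate 1, and the second day held the rest. With the day as a block, 1 probe set passed in place of 660 and was not among them, and the median difference of the 660, taken in its own direction, went from 0.35 (median SE 0.08) to 0.18 (median SE 0.18). None of the genes named for the mean passed with the day as a block (Camkk2 -0.20, Ndufs8 0.54, Igfbp2 0.76, Slc8a1 -0.60, Rps6 -0.12 and Rps3a -0.10, adjusted p = 0.99 to 0.998), nor did the ribosomal protein list (adjusted p = 0.931). The count was 410, 389, 383, 428, 388, 427, 404 and 434 without SHAM 0 h replicate 2, SHAM 12 h replicate 2, SHAM 24 h replicate 1, SHAM 48 h replicate 1, TOL 0 h replicate 2, TOL 3 h replicate 1 and TOL 24 h replicates 1 and 2.

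**Figure D3:**
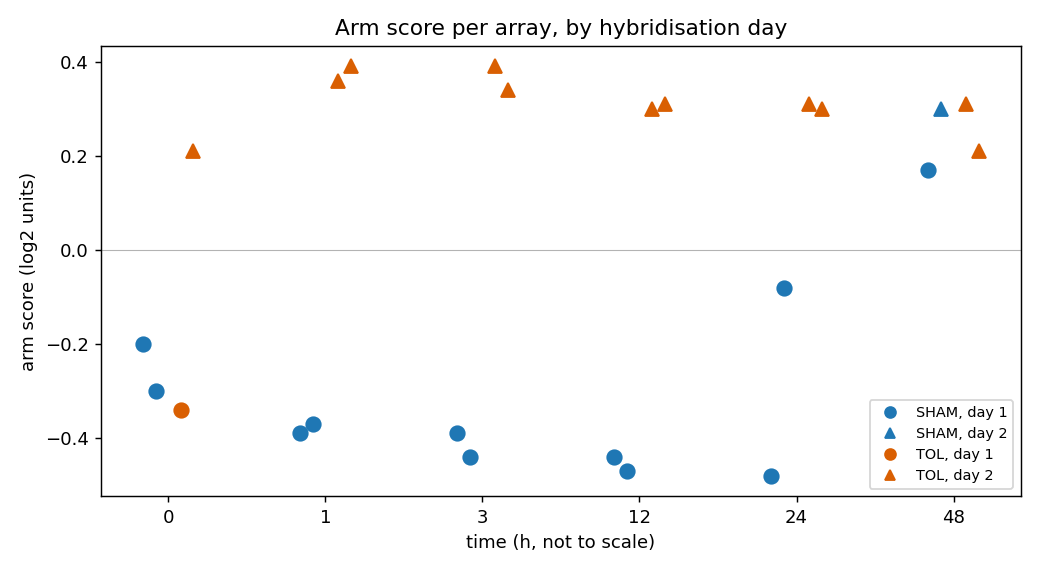
Arm score (mean log2 value over the 916 probe sets that differ between the arms at 1 to 24 h, signed so that higher means nearer TOL, less the mean of all arrays) against hours after the operation, with a point per array, circles for the first hybridisation day and triangles for the second. TOL 0 h replicate 1 of the first day scored -0.34 and replicate 2 of the second 0.21, while SHAM 48 h replicate 1 of the first day scored 0.17 and replicate 2 of the second 0.30.

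At 0 h, 5 probe sets were higher and 2 lower in TOL. They named Grk1, the rhodopsin kinase gene, at 159 ± 0.616 units in TOL against 267 ± 24.1 in SHAM (-0.75 ± 0.12, adjusted p = 0.026), and the sialyltransferase gene St6galnac3 at 219 ± 23.4 against 110 ± 1.34 units (0.98 ± 0.16, adjusted p = 0.04). The others were the smooth muscle myosin gene Myh11, at least 1.63-fold higher (adjusted p = 0.026), and Glyatl2, below the noise level in both arms. None of these 4 genes passed with the day as a block (adjusted p = 0.138 to 0.182). The differences of Grk1 and St6galnac3 were -0.75 and 0.98 without the block and -0.76 and 0.94 with it. Myh11 did not pass with the floor at the 40th percentile (adjusted p = 0.205) or with the pseudocount (adjusted p = 0.0502), and its fitted difference was 4.26 without SHAM 0 h replicate 1 and 2.07 without replicate 2. With the replicate as a block St6galnac3 (0.98) and Glyatl2 missed the threshold (adjusted p = 0.0533 each). Glyatl2 also missed it on the deposited scale, with median scaling, with the pseudocount and with trend and robust moderation (adjusted p = 0.105, 0.261, 0.297 and 0.506). St6galnac3 also missed it with median scaling (0.99, adjusted p = 0.0828), with the stricter filter (0.98, adjusted p = 0.0603) and on the deposited scale (1.26, adjusted p = 0.137), where Grk1 did too (-0.50, adjusted p = 0.597). Nor did any of the 4 without TOL 0 h replicate 1 (adjusted p = 0.0528 to 0.081), TOL 0 h replicate 2 (0.0836 to 0.17), either SHAM 3 h array (0.0524 to 0.0688) or either SHAM 12 h array (0.0567 to 0.0817). Grk1 was also lost without SHAM 0 h replicate 2, and Myh11 without either TOL 24 h array. St6galnac3 and Glyatl2 were also lost without either SHAM 0 h array or any array of TOL 1, 24 or 48 h. The count was 27 and 22 without SHAM 0 h replicates 1 and 2, 15 without TOL 0 h replicate 1, 10 within the first day alone, 18 without either SHAM 1 h array, 11 without any one of the SHAM 24 h or 48 h arrays, 3 without either TOL 24 h array, and 1 without any one of the SHAM 3 h or 12 h arrays or with the day as a block. On the deposited scale, where the median of all probe sets at 0, 1 and 48 h shifted by 0.23, 0.20 and -0.22, 87.5% of the calls at 0 h were higher, against 71.4% after quantile normalisation and 60% after median scaling.

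At the later single times few genes differed between the arms. At 1 h, 4 probe sets differed, naming Areg, a growth factor gene below the noise level in both arms (not passed with the pseudocount or with trend and robust moderation, adjusted p = 0.155 and 0.131), and the AAA ATPase gene Nvl. Nvl lay below the noise level in TOL (38.8 ± 3.24 against 74 ± 7.93 units) and was at least 1.79-fold lower there (adjusted p = 0.034). It did not pass with the day as a block (adjusted p = 0.16), though its fitted log2 difference, -0.93 without the block, was -1.08 with it. The call was also lost on the deposited scale (adjusted p = 0.35), with the stricter filter (adjusted p = 0.0559), with trend and robust moderation (adjusted p = 0.076) and without SHAM 1 h replicate 1, TOL 1 h replicate 1 or TOL 1 h replicate 2 (adjusted p = 0.209, 0.0704 and 0.0533). At 3 h, 1 probe set with no single gene name differed, and 0 genes, where 1024 probe sets passed limma's test at an unadjusted p under 0.05. The genes nearest the threshold at 3 h, none of which passed, were Sart1, Pld1, Apba3, Svop and Lgals9 (adjusted p = 0.065 each). At 12, 24 and 48 h, 29, 13 and 21 probe sets differed, with Tef among them each time, and 6, 3 and 18 did with the day as a block. Within the second day 38 did at 48 h. These counts turn on single arrays. The count at 1 h became 38 and 28 without SHAM 1 h replicate 2 and TOL 1 h replicate 1, 11 without SHAM 1 h replicate 1 and 9 without TOL 1 h replicate 2. Leaving out an array of another group gave up to 17. At 3 h it was 66 and 12 without SHAM 3 h replicates 1 and 2, 2 and 11 without TOL 3 h replicates 1 and 2, and 0 to 23 without an array of another group. At 12 h it was 13 and 52 without SHAM 12 h replicate 2 and TOL 12 h replicate 1. It was 62, 48 and 46 without an array of SHAM 24 h, SHAM 48 h and TOL 0 h, and 18 without one of TOL 1 h. At 24 h it was 27 and 40 without SHAM 24 h replicates 1 and 2 and 8 without an array of SHAM 12 h. At 48 h it was 38, 36 and 37 without SHAM 48 h replicates 1 and 2 and TOL 48 h replicate 2. The share of higher calls also moved. With the values as deposited it was 100%, 57.1% and 37.5% at 1, 12 and 48 h, against 75%, 69% and 57.1% after quantile normalisation, and median scaling gave 66.7% at 3 h.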

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

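Which tests were chosen after the result was seen: those of the hybridisation day and of an arm difference constant over time, that of the day for the SHAM 48 h arrays, that of the day for calcium handling genes at 24 h in TOL, and those of a lower share of neurons. The genes and lists in this part stand out because the time courses of the arms differed by a test of the difference itself.

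By the interaction F test the genes were Entpd2 (adjusted p = 5.9e-05), Areg (3e-04), Edn2 (0.00046), Sart1 (0.0011), Nupr1 (0.0019), Kcnj10 (0.0022), Serpinb9 (0.0041), F2rl1 (0.015), Chrna3 (0.017), Ccl3 (0.017), Tef (0.023) and Grk1 (0.027). Tef and Grk1 were above the noise level at every time in both arms. Areg at 1 h, Edn2 and Serpinb9 at 24 h and Ccl3 and Nupr1 at 48 h lay below it in both arms. With the floor at the 40th percentile Entpd2, Sart1, Kcnj10, Serpinb9, F2rl1 and Chrna3 did not pass (adjusted p = 0.272, 0.276, 0.529, 0.977, 0.0986 and 0.221), and with trend and robust moderation Areg, Edn2, Nupr1, Chrna3 and Ccl3 did not (0.565, 0.208, 0.18, 0.116 and 0.343), nor did Areg with the pseudocount (0.459). On the deposited scale F2rl1, Chrna3, Tef and Grk1 did not pass (0.264, 0.217, 0.146 and 0.651), and with the day as a block Grk1 did not (0.0564), though its difference between time courses at 12 h was 1.25 without the block and 1.23 with it. Leaving out 1 array ended the call of F2rl1 (SHAM 48 h replicate 1 or 2, 0.0508 and 0.0518), Ccl3 (the same arrays, 0.0838 and 0.0858), Chrna3 (SHAM 12 h replicate 2, 0.0547), Tef (SHAM 12 h replicate 2, 0.0547, and TOL 24 h replicates 1 and 2, 0.06 and 0.0544) and Grk1 (SHAM 0 h replicate 2, 0.076, SHAM 12 h replicates 1 and 2, 0.0718 and 0.0841, TOL 0 h replicates 1 and 2, 0.0699 and 0.0665, and TOL 12 h replicate 2, 0.0536). With median scaling Tef and Grk1 also missed the threshold (0.0504 each).

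By camera the lists whose change from 0 h differed between the arms were, at 3 h, immediate early genes (adjusted p = 0.0411, median 0.24) and ribosomal proteins (0.0468, -0.11), at 12 h, oxidative phosphorylation (0.0117, 0.16), and at 48 h, immediate early genes (0.00155, 0.40), microglia and macrophage markers (0.0348, 0.50), oligodendrocyte markers (0.00925, -0.48), ribosomal proteins (0.000188, 0.27) and oxidative phosphorylation (0.0246, 0.19). No single member passed limma's test in any of them. At an unadjusted p under 0.05, 5, 0, 2, 4, 4, 1, 12 and 4 members were higher and 0, 3, 0, 0, 0, 2, 0 and 1 lower, in the same order, and adjusted over the list alone 5 ribosomal protein genes were higher at 48 h and no member of the other lists passed. With an estimated correlation none held (adjusted p = 0.348, 0.534, 0.658, 0.141, 0.435, 0.548, 0.265 and 0.705 with an estimated correlation, in the same order). With the day as a block ribosomal proteins lost the call at 3 h (0.34). The deposited scale ended the calls of immediate early genes (0.0649) and ribosomal proteins (0.194) at 3 h, oxidative phosphorylation at 12 and 48 h (0.0928 and 0.243) and oligodendrocyte markers (0.175), and on it the medians of immediate early genes and ribosomal proteins at 48 h and of oxidative phosphorylation at 12 and 48 h changed sign (-0.07, -0.08, -0.05 and -0.19). The floor at the 40th percentile ended those of immediate early genes and ribosomal proteins at 3 h (0.0772 and 0.128), the replicate as a block that of ribosomal proteins at 3 h (0.0518), and the stricter filter that of microglia and macrophage markers (0.0634). Median scaling ended those of ribosomal proteins at 3 h (0.456), microglia and macrophage markers (0.0525) and oligodendrocyte markers (0.0758). The ribosomal protein list at 48 h kept its call without each of the 24 arrays. The other lists did not. The microglia list lost it without SHAM 48 h replicate 2 (0.489), SHAM 0 h replicate 1 (0.216), TOL 48 h replicate 1 (0.169), TOL 0 h replicate 2 (0.115) or TOL 12 h replicates 1 or 2 (0.0565 and 0.0546), immediate early genes at 48 h without TOL 48 h replicate 1 (0.0506), and oligodendrocyte markers without SHAM 48 h replicate 1, TOL 0 h replicate 2 or TOL 48 h replicate 2 (0.107, 0.0726 and 0.0949). Oxidative phosphorylation lost it at 12 h without SHAM 0 h replicate 2, TOL 0 h replicate 2 or TOL 12 h replicate 1 (0.127, 0.178 and 0.345) and at 48 h without SHAM 0 h replicate 2, SHAM 48 h replicate 1, TOL 0 h replicate 2 or TOL 48 h replicate 2 (0.169, 0.0537, 0.148 and 0.664). Both calls at 3 h were lost without many of the arrays, most of all TOL 0 h replicate 1 (0.17 and 0.42).

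Many probe sets differed between the arms over all times. Of 100 draws of arm labels within each time, 1, the real one, gave as many as 660, and the highest other gave 24. A random split thus rarely gives this. The real labels nearly follow the day, so the draws do not tell arm from day. An arm difference constant over time with no day effect is excluded. Probe sets called from 1 to 24 h had a signed median of 0 at 48 h. It was 0.49, 0.52, 0.45 and 0.29 at 1, 3, 12 and 24 h, each called without that time. The day of hybridisation may account for the arm difference. On the 916 probe sets called from 1 to 24 h (median size 0.47), the TOL 0 h array of the later day exceeded that of the earlier day by 0.36, but the SHAM 48 h array of the later day exceeded its partner by 0.07, so arm and day cannot be told apart. An arm difference that changes with time, or is constant beside a day effect, stays open and was not tested.

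The SHAM 48 h arrays differed in microglia and macrophage genes. Over the 11 such genes called in TOL at 48 h, replicate 2 lay below replicate 1 in 11, by a median of -0.93, and was -0.94 from the TOL mean against -0.12 for replicate 1. Replicate 2 is the only SHAM array of the later day, and with the day as a block TOL exceeded SHAM by a median of 0.82 (median SE 0.44), so the day and a difference between the samples cannot be told apart. A weaker response of the second sample could be the source, but 12 of 19 neuronal and calcium genes fell less in it (exact sign test, two-sided p = 0.359). Their median fall was no smaller (-0.83 against -0.72, median SE 0.16), so this cannot be told apart from an equal response. In 7 heat shock genes the median rise was 0.75 against 0.90, a gap not tested.

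Calcium handling genes were lower at 24 and 48 h in both arms. In SHAM at 24 h the day is excluded, as the arrays compared share 1 day. Within 1 day all called genes (SHAM 48 h 11, TOL 48 h 12, TOL 24 h 8) kept at least 50% of their fall. A call needs the arrays of both days to agree, so this hardly tests the day. With the day as a block the list passed camera each time (adjusted p at most 0.000464), which argues against the day. A lower share of neurons alone would raise the markers of all other cell types alike, which was tested at 48 h only. In TOL the median of 31 microglia genes exceeded that of 54 astrocyte, oligodendrocyte and vessel genes by 0.62 (95% interval over genes 0.15 to 1.23). The median of the other types there was 0.07 (-0.05 to 0.29). A separate rise of microglia would give this gap with or without fewer neurons, so the test cannot exclude a lower share. In SHAM the difference was 0.43 (-0.24 to 1.15), an interval too wide to decide, and the other types rose by 0.23 (0.12 to 0.36). These intervals measure the spread over genes and not between samples. Lower expression per neuron was not tested and stays open.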

How the results depend on the processing

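The additive models, the F tests of 1, 3 and 12 h, the arm difference over 1 to 24 h and the list tests with the day as a block, under other scalings and without each array were chosen after the result was seen. For the 107 pairs of named gene and comparison, 998 of 1058 values under alternatives other than leaving out an array kept their direction and call, 60 kept the direction only and 0 reversed. Without each array in turn, 2496 of 2568 did and 72 kept the direction only. Of 88 list calls, 54 held on the deposited scale, 71 with median scaling, 80 with the floor at the 40th percentile, 77 with the day as a block and 37 without each of the 24 arrays. On the deposited scale, where all genes shift together, the median of 20 of the 88 lists changed sign. Camera's direction turned for 1 call without SHAM 48 h replicate 2 and for 1 without TOL 48 h replicate 2. With an estimated correlation 8 list calls held. The floor at the 10th percentile lies below 0, so it has no log2 and gives no value. The fluidics run as a fixed block could not be fitted. Where no reason is given below, the cause was not tested.

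The deposited scale called fewer probe sets: 421 for the SHAM time course, 348 for TOL and 100 for the mean arm difference. In SHAM it gave 33, 45, 143, 239 and 347 at 1, 3, 12, 24 and 48 h. In TOL it gave 40, 168 and 306 at 3, 24 and 48 h. Between the arms it gave 14 and 8 at 12 and 24 h, but more at 0 and 3 h (8 and 2). Per gene, by construction, counts were 636, 468, 14 for the interaction, 4 at 0 h and 384 for the mean. Without the TOL 24 and 48 h arrays, F tests of 1, 3 and 12 h gave 297 in SHAM and 235 in TOL, with fewer contrasts tested. Median scaling gave 9 between the arms at 3 h and the pseudocount 2. The 40th percentile floor gave 10 for the interaction, 14 at 0 h, and 0, 60 and 5 between the arms at 3, 12 and 24 h. The stricter filter gave 10 for the interaction, 3 at 0 h, and 1, 0, 17, 2 and 7 at 1, 3, 12, 24 and 48 h, and no filter 0 at 3 h. The replicate number does not pair the arrays (correlations of residuals between 66 pairs of groups from -0.168 to 0.179), and as a replicate block it gave 2 at 3 h and 8 at 24 h between the arms.

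With the day as a block the counts were 1 at 0 h and 1 for the mean, 551 at 48 h in SHAM, 46, 153, 326 and 344 at 3, 12, 24 and 48 h in TOL, and 2, 6 and 3 between the arms at 3, 12 and 24 h. An additive model of time, arm and day gave 0 for arm and day, against 538 for arm alone and 1050 for day alone. So it cannot separate them. The fluidics run as a random block gave 42 for the interaction, 1231 for the mean, 224 at 3 h in SHAM, and 40, 27, 68 and 24 between the arms at 1, 3, 12 and 24 h. Most groups lie in 1 run, so the within-run correlation (-0.081) cannot exclude a run effect. Trend and robust moderation gave 14 for the interaction, 4 at 0 h, and 14, 52 and 7 at 3, 12 and 24 h.

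Leaving out each array in turn gave 828 to 1166 for the SHAM time course, 576 to 884 for TOL, 20 to 53 for the interaction, 383 to 936 for the mean and 1 to 27 at 0 h. In SHAM it gave 47 to 65, 71 to 174, 176 to 415, 330 to 671 and 382 to 955 at 1, 3, 12, 24 and 48 h, in TOL 48 to 122, 33 to 107, 110 to 317, 171 to 543 and 199 to 539, and between the arms 5 to 38, 0 to 66, 13 to 62, 8 to 40 and 18 to 38.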

Other observations

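Several further lists passed camera. In TOL at 12 h, genes of cholesterol synthesis were lower (2 of 19 measured, 4 adjusted over the list alone, median -0.38, adjusted p = 0.0124; adjusted p = 0.354 with an estimated correlation), among them the farnesyl diphosphate synthase gene Fdps (54.7 ± 33.6 against 250 ± 83.9 units, -2.30 ± 0.46, adjusted p = 0.012). Fdps lost its call with the day as a block (-1.98, adjusted p = 0.0617) and without TOL 0 h replicate 1 or TOL 12 h replicate 2 (-1.95 and -1.63, adjusted p = 0.124 and 0.122), and was -2.97 without TOL 12 h replicate 1. The list lost its call without TOL 0 h replicate 2 (adjusted p = 0.0968) and on the deposited scale (0.0649). At 48 h camera placed it lower again (0 of 19 by limma, 0 adjusted over the list alone, 7 unadjusted, median -0.39, adjusted p = 0.00925; adjusted p = 0.348 with an estimated correlation), a call lost on the deposited scale (0.0561) and without TOL 0 h replicate 2 or TOL 48 h replicate 2 (0.0721 and 0.318). At 48 h in TOL, genes of the GABA system (3 of 31 fell, 3 adjusted over the list alone, median -0.33, adjusted p = 0.0398; adjusted p = 0.21 with an estimated correlation) and of voltage-gated ion channels (1 of 39 fell, 1 adjusted over the list alone, median -0.36, adjusted p = 0.0302; adjusted p = 0.222 with an estimated correlation) were lower, and on the deposited scale neither list passed (0.0619 and 0.13). With low means at the noise level the channel median was -0.22. The channel call was lost with median scaling (0.0561) and without TOL 0 h replicate 1 (0.078), and the GABA call with the floor at the 40th percentile (0.0562) and without TOL 0 h replicate 1, TOL 0 h replicate 2 or TOL 48 h replicate 2 (0.072, 0.0913 and 0.223).

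Stress and protein turnover lists passed upward by small amounts in both arms after normalisation. In SHAM at 24 h, endoplasmic reticulum stress genes were higher (4 of 17 rose, 4 adjusted over the list alone, median 0.24, adjusted p = 0.0428; adjusted p = 0.388 with an estimated correlation), and so were proteasome subunits (2 of 24, 2 adjusted over the list alone, median 0.25, adjusted p = 0.00925; adjusted p = 0.38 with an estimated correlation). Neither passed on the deposited scale (0.106 and 0.175), with median scaling (0.111 and 0.153), without SHAM 24 h replicate 1 (0.272 and 0.12) or without SHAM 0 h replicate 1 (0.0502 and 0.0884). The former also failed with the floor at the 40th percentile (0.0526) and without SHAM 0 h replicate 2 or TOL 0 h replicate 2 (0.095 and 0.0583). In TOL, 2 of the 17 endoplasmic reticulum stress genes rose at each of 12, 24 and 48 h, and 2, 2 and 3 did adjusted over the list alone. The medians were 0.19, 0.14 and 0.19 (0.12 at 48 h with low means at the noise level), with adjusted p = 0.0194, 0.0337 and 0.0463 (adjusted p = 0.354, 0.388 and 0.388 with an estimated correlation). None of these calls held on the deposited scale (medians -0.16, 0.00 and -0.07, adjusted p = 0.122, 0.106 and 0.233) or without TOL 0 h replicate 2 (0.339, 0.386 and 0.442). Those at 24 and 48 h were lost with median scaling (0.0563 and 0.1) and with the floor at the 40th percentile (0.0588 and 0.0756), and that at 48 h with the replicate as a block (0.0519) or without any of 12 arrays. Of the 24 proteasome subunits, 3 rose in TOL at 24 h (5 adjusted over the list alone, median 0.18, adjusted p = 0.00774; adjusted p = 0.378 with an estimated correlation) and 1 at 48 h (0 adjusted over the list alone, median 0.13, adjusted p = 0.0468; adjusted p = 0.497 with an estimated correlation). Neither held on the deposited scale (medians 0.05 and -0.15, adjusted p = 0.148 and 0.856) or without TOL 0 h replicate 2 (0.0785 and 0.217), and that at 48 h was lost with median scaling (0.326) or without any of 9 arrays. The interferon and class I antigen presentation list rose in SHAM at 48 h (2 of 17, 4 adjusted over the list alone, median 0.52, or 0.29 with low means at the noise level, adjusted p = 0.0123; adjusted p = 0.222 with an estimated correlation), and not without SHAM 0 h replicate 2 or SHAM 48 h replicate 2 (0.0578 and 0.0717). In TOL it rose at 48 h too (3 of 17, 3 adjusted over the list alone, median 0.18, adjusted p = 0.0249; adjusted p = 0.283 with an estimated correlation), but not on the deposited scale (median -0.07, adjusted p = 0.0686) or without TOL 0 h replicate 2 or TOL 48 h replicate 1 (0.276 and 0.0553). In TOL, apoptosis and p53 target genes rose at 12 h (2 of 19, 2 adjusted over the list alone, median 0.22, adjusted p = 0.0483; adjusted p = 0.228 with an estimated correlation), which did not hold on the deposited scale (median -0.08, adjusted p = 0.149), with median scaling (0.0559), with the stricter filter (0.0985), with no filter (0.0549), with the replicate as a block (0.0518), with the day as a block (median 0.08, adjusted p = 0.0709) or without any of 18 of the arrays, TOL 12 h replicate 1 the most (0.158). For hypoxia and glycolysis genes in TOL at 1 h, camera passed upward although no member did (0 of 27 by limma, 0 adjusted over the list alone, 4 unadjusted, median 0.13, adjusted p = 0.0411; adjusted p = 0.332 with an estimated correlation), which did not hold on the deposited scale (0.129), with median scaling (0.123) or without SHAM 0 h replicates 1 or 2 (0.0502 and 0.0547), TOL 0 h replicates 1 or 2 (0.196 and 0.0643) or TOL 1 h replicates 1 or 2 (0.0941 and 0.0889). At 3 h camera passed upward again, with 0 of 27 by limma, 0 adjusted over the list alone and 5 higher and 1 lower unadjusted (median 0.11, adjusted p = 0.0317; adjusted p = 0.304 with an estimated correlation). That call was lost on the deposited scale (median -0.03, adjusted p = 0.269), with median scaling (0.0906) and without TOL 0 h replicates 1 or 2 or TOL 3 h replicate 2 (0.15, 0.0643 and 0.24).

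Between the arms, the ribosomal protein list passed in both directions. It was lower in TOL at 3 h (0 of 36 by limma, 8 adjusted over the list alone, 15 unadjusted, median -0.22, adjusted p = 4.06e-07; adjusted p = 0.122 with an estimated correlation), and the call held with the day as a block (0.0153). Camera also placed it lower at 0, 1 and 12 h (0 of 36 by limma each time, 3, 0 and 1 adjusted over the list alone). The medians were -0.08, -0.19 and -0.14, with adjusted p = 0.0141, 6.94e-05 and 0.00424 (adjusted p = 0.405, 0.222 and 0.38 with an estimated correlation). With the day as a block these 3 calls were lost (medians -0.06, -0.10 and -0.04, adjusted p = 0.299, 0.157 and 0.707). The call at 0 h was also lost on the deposited scale (median 0.06, adjusted p = 0.0556) and without SHAM 0 h replicate 2 or TOL 0 h replicate 2 (0.127 and 0.423). At 48 h camera placed the list higher in TOL (0 of 36 by limma, 0 adjusted over the list alone, 8 unadjusted, median 0.10, or 0.05 with low means at the noise level, adjusted p = 0.00353; adjusted p = 0.366 with an estimated correlation). That call held with the day as a block (median 0.17, adjusted p = 4.89e-05), but not on the deposited scale (median -0.02, adjusted p = 0.0902) or without SHAM 48 h replicate 2 or TOL 48 h replicate 2 (0.248 each). At 0 h, camera placed oligodendrocyte markers higher and blood cell markers lower, though no member of either list passed. Limma passed 0 of 14 for oligodendrocyte markers (0 adjusted over the list alone, 0 unadjusted, median 0.26, adjusted p = 0.0255; adjusted p = 0.637 with an estimated correlation) and 0 of 11 for blood cell markers (1 unadjusted, median -0.35, adjusted p = 0.0302; adjusted p = 0.21 with an estimated correlation). The oligodendrocyte call was lost on the deposited scale (0.177), with median scaling (0.144) and without SHAM 0 h replicate 1 or TOL 0 h replicate 2 (0.206 and 0.427), and the blood cell call with the day as a block (0.119), with the floor at the 40th percentile (0.138), with no filter (0.0697) and without SHAM 0 h replicate 1, SHAM 0 h replicate 2, TOL 0 h replicate 1 or TOL 0 h replicate 2 (0.073, 0.113, 0.0746 and 0.159). At 3 h camera also placed oligodendrocyte markers higher (0 of 14 by limma, 0 adjusted over the list alone, 3 unadjusted, median 0.24, adjusted p = 0.0298; adjusted p = 0.651 with an estimated correlation), a call lost on the deposited scale (0.13), with median scaling (0.0563) and without SHAM 3 h replicate 1 or TOL 3 h replicate 1 (0.174 and 0.101). Immediate early genes were also placed lower at 0 h (0 of 32 by limma, 0 adjusted over the list alone, 1 unadjusted, median -0.17, adjusted p = 0.0468; adjusted p = 0.354 with an estimated correlation). That call was lost on the deposited scale (median 0.04, adjusted p = 0.0802), with median scaling (0.0667), with the floor at the 40th percentile (0.0993), with the stricter filter (0.0618) and without any of 13 arrays, TOL 0 h replicate 1 the most (0.532).

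Further lists differed between the arms by camera, mostly at 48 h. Placed higher in TOL at 48 h were microglia and macrophage markers (0 of 31 by limma, 2 adjusted over the list alone, median 0.32, adjusted p = 0.00378; adjusted p = 0.332 with an estimated correlation), reactive glia (0 of 28, 3 adjusted over the list alone, median 0.27, or 0.15 with low means at the noise level, adjusted p = 0.018; adjusted p = 0.63 with an estimated correlation) and immediate early genes (0 of 32, 0 adjusted over the list alone, median 0.13, adjusted p = 0.0141; adjusted p = 0.265 with an estimated correlation). None of the 3 held without SHAM 48 h replicate 2 (0.569, 0.854 and 0.185) or TOL 48 h replicate 1 (0.105, 0.628 and 0.4). The reactive glia call was also lost with the stricter filter (0.0659), and the immediate early median was -0.08 on the deposited scale. Antioxidant and metal-binding genes were placed higher at 24 h (0 of 35, 2 adjusted over the list alone, median 0.14, adjusted p = 0.0154; adjusted p = 0.137 with an estimated correlation) and 48 h (1 of 35, 3 adjusted over the list alone, median 0.10, adjusted p = 0.0249; adjusted p = 0.17 with an estimated correlation). The former was lost without SHAM 24 h replicate 1 (0.0546). The latter was lost on the deposited scale (median -0.12, adjusted p = 0.12) and without SHAM 0 h replicate 1, SHAM 48 h replicate 2 or TOL 48 h replicate 1 (0.0501, 0.237 and 0.177). Oxidative phosphorylation was placed lower at 1 h (0 of 58, 0 adjusted over the list alone, median -0.13, adjusted p = 0.0176; adjusted p = 0.687 with an estimated correlation) and higher at 48 h (0 of 58, 0 adjusted over the list alone, median 0.10, adjusted p = 0.0477; adjusted p = 0.743 with an estimated correlation). Neither held on the deposited scale (medians 0.02 and -0.08, adjusted p = 0.111 and 0.452). That at 1 h was lost with the day as a block (median -0.11, adjusted p = 0.133) and without SHAM 1 h replicate 1 or TOL 1 h replicate 2 (0.0666 and 0.245), and that at 48 h with the replicate as a block (0.0519) and without any of 15 arrays. Cholesterol synthesis was placed lower at 12 h (0 of 19, 4 lower and 1 higher adjusted over the list alone, median -0.15, adjusted p = 0.0468; adjusted p = 0.435 with an estimated correlation) and 48 h (0 of 19, 0 adjusted over the list alone, median -0.31, adjusted p = 0.0223; adjusted p = 0.388 with an estimated correlation). Both were lost on the deposited scale (0.0764 and 0.0798) and with the day as a block (medians -0.29 and -0.22, adjusted p = 0.1 and 0.0612). That at 12 h was lost with the pseudocount (0.0539) and without any of 13 arrays, and that at 48 h without SHAM 48 h replicate 1 or TOL 48 h replicate 2 (0.211 and 0.726).

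Astrocyte markers, cell cycle genes, choroid plexus and ependymal markers, endothelial and vascular markers and growth factors had 0 camera calls in 22 tests each (lowest adjusted p = 0.192, 0.133, 0.0901, 0.215 and 0.354). At an unadjusted p under 0.05, camera called 1, 2, 2, 0 and 0 of these tests, and fry called 2, 1, 0, 0 and 0.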
